A study of Mus musculus with 16 samples.

How the data were processed

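The 16 samples were mouse dendritic cells grown from bone marrow of male C57/B6 mice with GM-CSF (20 ng/ml) for 10 days and then treated for 24 h, per the labels' protocols. They fall into 4 groups of 4 numbered biological replicates, which are mock-treated cells (mock), cells given PA (0.5 mM, bound to bovine serum albumin at a molar ratio of 6 to 1), cells given IMQ, and cells given both. PA is read here as palmitic acid and IMQ as imiquimod, an agonist of the RNA sensor TLR7, from knowledge of the study. The dose of IMQ is given as 3 uM in one label and as 3 ug/ml in another. The labels do not state whether mock cells received albumin, and the protocol also mentions a fatty acid abbreviated OA that no sample here received.

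Total RNA (200 ng per sample) was made into biotin-labelled DNA with a whole-transcript kit and hybridised to 1-colour Affymetrix mouse gene arrays, per the labels' protocols. The deposited values are on a log2 scale, and the submitters' processing notes name RMA and affy, without versions. RMA corrects the background, normalises arrays by quantiles and summarises the probes of each probe set. No genome build was given in the sources used here. The table held 41345 probe sets on 16 arrays, with values from 0.628 to 13.5 and none missing. An array has no read depth, so the number of arrays limits the precision.

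Gene names came from the platform annotation table and were checked by gene number against a RefSeq table (assembly GRCm38.p6), which was used for names only. Of the probe sets, 23521 had 1 symbol, 1814 had several and 16010 had none listed. The last 2 kinds were left out. Of the single-symbol probe sets, 23328 were found in the reference by gene number and 193 were not, and 0 symbols needed an update. For the 1082 genes with more than 1 probe set, the one with the highest mean over all arrays was used, which left 22180 genes.

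A linear model with 4 group means was fitted to all 16 arrays with limma 3.58.1 in R 4.3.3, with moderated variances (eBayes, 12 residual and 2.96 prior degrees of freedom). Contrasts were PA minus mock, IMQ minus mock, IMQ and PA minus IMQ, IMQ and PA minus PA, and the interaction, which is the PA change with IMQ minus the PA change without it. All limma tests were two-sided. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested, with no threshold on size and no filter on dim genes. Changes are differences of log2 values, with the standard error of the fit after ±. Gene lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over all 120 tests (24 lists in 5 comparisons). The lists covered the PERK-ATF4 branch, ER folding, cytokines, chemokines, NF-kB targets and feedback, type I interferon genes, dendritic cell maturation, MHC class II, glycolysis, oxidative phosphorylation with the citrate cycle, fatty acid oxidation with PPAR targets, cholesterol synthesis, fatty acid synthesis, NRF2 targets, the cell cycle, p53 with apoptosis and ribosomal proteins. Others held markers of macrophages, conventional and plasmacytoid dendritic cells, neutrophils, mast cells with basophils and eosinophils, lymphocytes and erythroid cells. Camera compares a list with all other genes. The same test with an estimated correlation, and fry, which asks whether the genes of a list move on balance one way, were alternatives. The lists held 380 distinct genes, of which 345 were measured. Another 35 were not analysed here, 12 of them because their probe set carried several symbols.

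The rule for naming genes was fixed before the data were examined. It admitted the 6 highest and the 6 lowest log2 changes among called genes whose replicate values did not overlap between the groups compared (for the interaction, among called genes), leaving out predicted or unnamed loci. It admitted up to 3 called members of a list in its main direction and 1 in the other by size. It also took 14 preset genes in every comparison, namely Il23a, Il12b, Il1b, Il6, Tnf, Il10, Ddit3, Atf3, Trib3, Xbp1, Hspa5, Cpt1a, Plin2 and Hmox1. A gene was called dim where all 4 group means lay below 4.93, the 95th percentile of the means of 1409 odorant, vomeronasal and other sensory receptor genes, most of which should be silent in these cells. There were 8614 such genes. Where 1 of 2 groups compared had a mean below that level, the change of a gene named for it is given as a lower bound of its size.

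The steps were tested on simulated data for 22180 genes, of which 67, 67 and 66 carried a known change of 0.5, 1 and 2 on the log2 scale. For PA versus mock, 67.2%, 97.0% and 100% of these were recovered, and 7.37% of calls were false. For the interaction the shares recovered were 64.2%, 92.5% and 100%, with 7.57% of calls false. Simulated lists without a change gave 0 camera calls in both. The noise of each simulated gene was drawn independently, so these rates do not cover genes that vary together, as those of a list may.

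Alternatives were repeated quantile normalization, equal array medians, leaving out dim genes, the mean of a gene's probe sets, a variance trend with robust moderation, array weights, fits of only the groups compared, the replicate number as a block, a size threshold of 1 on the log2 scale, and leaving out each array in turn. After the data were seen, 2 more were added, since several arrays without IMQ carried part of the IMQ pattern. The implied share of that pattern was computed over 75 genes called higher with IMQ whose linear IMQ mean exceeded the lowest of the 8 arrays without IMQ by more than 3 on the log2 scale. For each gene it is the linear value minus that lowest value, divided by the IMQ mean minus that lowest value, and the median over genes was taken. One addition used this share as a covariate and the other left out the arrays whose share was over 2%. Figures were drawn with matplotlib 3.10.9.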

Results

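Gene expression was measured on 16 whole-transcript arrays of mouse dendritic cells grown from bone marrow with GM-CSF, with 4 arrays in each cell of a design that crossed palmitic acid (PA), a saturated fatty acid, with imiquimod (IMQ), a TLR7 agonist. The design asks how each stimulus changed expression alone and how the fatty acid changed the response to the agonist. Values are log2 RMA values of 22180 genes, and n = 4 in every group. The labels call the replicates biological without saying which animals or cultures they came from, so the p-values measure only the spread between these arrays. Pearson correlations between arrays of 1 group, across genes, lay between 0.994 and 0.996, and 0 pairs of arrays held identical values. The first principal component held 66.1% of the variance and separated arrays with IMQ (34.1 to 38.9) from arrays without it (-40.7 to -33.6). The second held 10.8% and separated IMQ alone (17.8 to 23.7) from IMQ with PA (-23.6 to -17.5), while the mock arrays (-1.40 to 5.66) and PA arrays (-3.75 to -1.53) lay between.

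The arrays without IMQ differed among themselves in inflammatory genes, in a way that did not follow their group. Il6, a cytokine of the acute response, read 7.57, 7.90 and 7.71 in mock replicates 1 to 3 and 4.32 in mock replicate 4. It read at most 4.12 in PA replicates 1 and 2 and 7.43 and 8.22 in PA replicates 3 and 4, against at least 11.9 in the IMQ arrays. Il1b, the precursor of interleukin 1 beta, read 11.1, 11.3, 11.1 and 9.40 in the mock arrays and 9.86, 9.67, 10.7 and 11.2 in the PA arrays. Over 75 genes raised by IMQ, the median implied share of the IMQ level was 4.15%, 4.74%, 5.23% and 0.486% in mock replicates 1 to 4 and 0.80%, 0.703%, 2.53% and 3.13% in PA replicates 1 to 4.

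**Figure D1:**
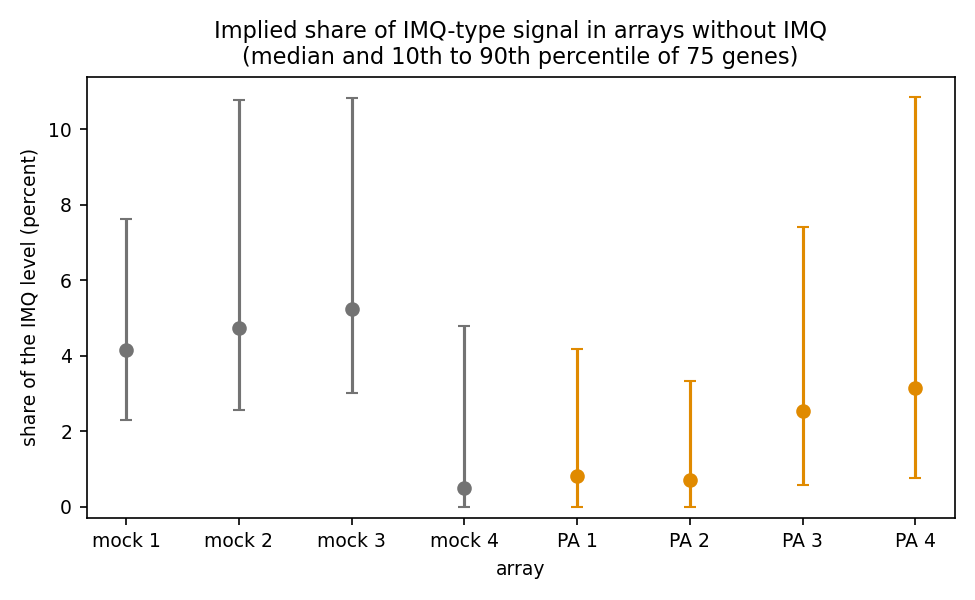
Implied share of the IMQ level (percent, vertical axis) in each of the 8 arrays without IMQ (horizontal axis), with points at the median and bars from the 10th to the 90th percentile of 75 genes raised by IMQ. Mock replicates 1 to 3 lie between 4.15% and 5.23%, mock replicate 4 at 0.486%, and the PA arrays between 0.703% and 3.13%.

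**Figure D2:**
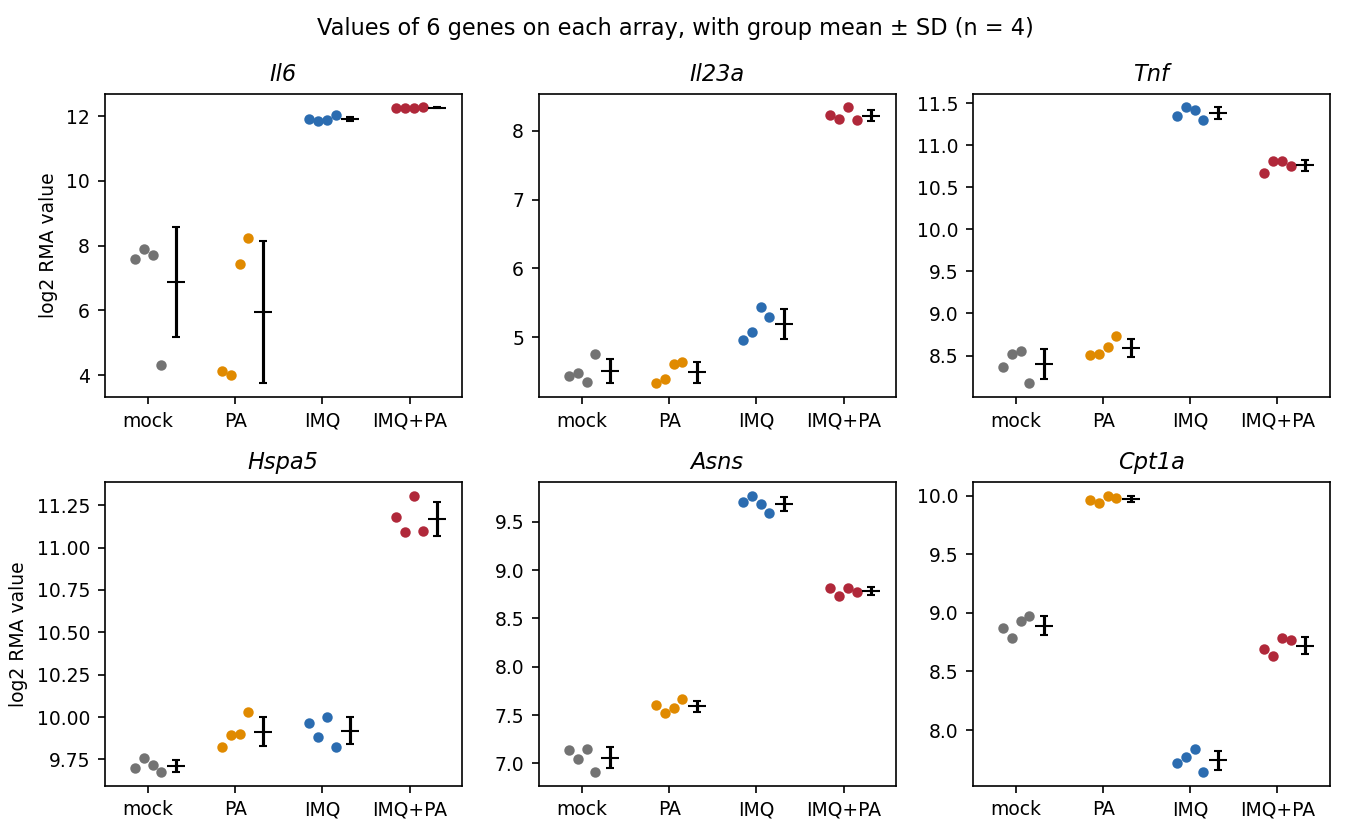
Log2 RMA values (vertical axes) of 6 genes on each array by group (horizontal axes), with points for arrays and dashes with bars for the group mean ± SD (n = 4). Il23a reached a mean of 8.22 with IMQ and PA against 5.19 with IMQ alone, while Asns was lower with both (8.79) than with IMQ alone (9.69).

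The largest rises with PA alone were in genes of lipid handling. Angptl4, which encodes a secreted inhibitor of lipoprotein lipase, rose 5.78-fold (log2 change 2.53 ± 0.13, limma adjusted p = 4.48e-08). Cpt1a, the enzyme that passes long-chain fatty acids to carnitine for entry into mitochondria, rose by 1.08 ± 0.05 on the log2 scale (adjusted p = 4.35e-08), and Plin2, a coat protein of lipid droplets, by 1.03 ± 0.05 (adjusted p = 3.13e-08). The platelet chemokine gene Ppbp (1.03 ± 0.12), the AP-1 subunit Fos (1.00 ± 0.07) and Oplah, an enzyme of the glutathione cycle (0.98 ± 0.08), completed the 6 largest rises among genes whose replicates did not overlap. Lox, which encodes a collagen-crosslinking oxidase, had a log2 change of -0.92 ± 0.10 (adjusted p = 0.000194). The falls of Taar7d (-1.32 ± 0.23) and Olfr1537 (-1.10 ± 0.16), both sensory receptor genes, lay in the dim range in all groups. In total limma called 331 genes, 233 higher and 98 lower, of which 8 changed by at least 1 on the log2 scale. Among the lower calls 38 of 98 were dim, a share like that of all genes tested (8614 of 22180). Among the higher calls 6 of 233 were dim. With the median of each array set equal, 266 were higher and 60 lower, a share higher of 81.6% against 70.4%. In the other comparisons dim genes were a smaller part of the lower calls. They were 270 of 3961 for IMQ versus mock, 187 of 2093 for IMQ and PA versus IMQ, 278 of 4114 for IMQ and PA versus PA and 98 of 1555 for the interaction.

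Of the lists that PA raised, the fatty acid oxidation and PPAR target list had 10 of 19 measured genes called higher and 0 lower (median log2 change 0.24). Cholesterol synthesis had 11 of 16 called higher (median 0.33), with Cyp51 (0.52 ± 0.07), Fdps (0.50 ± 0.08) and Fdft1 (0.46 ± 0.05), which act along the pathway to sterols. The NRF2 antioxidant list had 8 of 12 higher, among them glutathione reductase (Gsr, 0.36 ± 0.05) and the glutathione synthesis gene Gclc (0.35 ± 0.06). Fatty acid synthesis and desaturation had 5 of 11 higher, including the desaturase Fads2 (0.50 ± 0.08). In the list of the PERK-ATF4 branch of the unfolded protein response, 7 of 21 rose, with asparagine synthetase (Asns, 0.53 ± 0.06), the serine synthesis gene Psat1 (0.45 ± 0.06) and the amino acid transporter Slc7a5 (0.41 ± 0.08). Camera placed these 5 lists higher, with adjusted p from 8.34e-22 to 3.13e-09, and all 5 held with an estimated correlation. In the list of ER chaperones and ER-associated degradation, 5 of 24 rose, among them Derl3 (0.73 ± 0.12), Dnajb9 (0.40 ± 0.06) and Creld2 (0.29 ± 0.05). Camera called that list (adjusted p = 1.64e-07), and the call was lost at an adjusted p = 0.0694 with an estimated correlation. Adjusted over the list alone, the genes called higher were 13, 14, 11, 10, 12 and 10 in the 6 lists in the order given here.

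Camera placed 5 lists lower with PA. The chemokine list had 1 of 15 genes called lower, Ccl17 (-0.42 ± 0.04), at a median of -0.27 (adjusted p = 0.127 with an estimated correlation). The type I interferon list had 3 of 18 lower, including the transcription factor Irf7 (-0.31 ± 0.06; adjusted p = 0.471 with an estimated correlation). The macrophage markers had 1 of 12 lower, the scavenger receptor Marco (-0.56 ± 0.10; adjusted p = 0.186 with an estimated correlation). Neutrophil markers (median -0.11) and conventional dendritic cell markers (median -0.11) had 0 genes called over all genes and held with an estimated correlation. Some markers in both lists were dim, and the mean of the neutrophil list (-0.27) lay further below 0 than its median. Adjusted over the list alone, 2 chemokines, 4 interferon genes, 3 macrophage markers, 0 neutrophil markers and 1 dendritic cell marker were lower. The largest shares of IMQ-type signal were in 3 mock arrays, and with that share as a covariate the chemokine median was -0.02 and the interferon median 0.05, neither called. Under the same covariate the cytokine list (median 0.20, adjusted p = 0.000491) and the NF-kB list (median 0.06, adjusted p = 0.0137) were called higher, as were Il12b (0.25, adjusted p = 0.0177) and Tnf (0.33, adjusted p = 0.0134). These results do not test the lists, since the share was computed in part from members of the cytokine, chemokine, NF-kB and interferon lists. The direction of the NF-kB list turned with the setting. It was called higher without the arrays whose share was over 2% (median 0.11, adjusted p = 0.000237), which kept the mock array with the lowest share, and lower with repeated quantile normalization (median -0.06, adjusted p = 0.0169) and without mock replicate 4 (median -0.07, adjusted p = 0.000665). In the fit without these changes the cytokine list was not called (camera adjusted p = 0.822), though Il1f9, which encodes IL-36 gamma (0.58 ± 0.07), and the interleukin 1 antagonist Il1rn (0.28 ± 0.05) rose.

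With PA alone Il6 (-0.93 ± 0.88), Il1b (-0.36 ± 0.36), Il23a (-0.01 ± 0.11), Il12b (-0.01 ± 0.12), Tnf (0.19 ± 0.08) and Il10 (-0.11 ± 0.14) were not called, Il23a and Il10 with both means in the range of sensory receptor genes, nor were Ddit3 (0.24 ± 0.07), Trib3 (0.23 ± 0.07), Hspa5 (0.20 ± 0.06), Hmox1 (0.13 ± 0.04), Atf3 (-0.05 ± 0.04) and Xbp1 (0.02 ± 0.04). With a variance trend and robust moderation Ddit3 (adjusted p = 0.0190), Hspa5 (0.0163) and Hmox1 (0.00953) were called higher. Without the arrays whose share was over 2%, 1 mock and 2 PA arrays were left, the lone mock array was taken to vary like the other groups, and 15 genes were called, among them Angptl4, Cpt1a, Plin2, Fos and Lox. With the share as a covariate and all arrays kept, 225 were called, 184 of them among the 331. All other genes named here as changed by PA alone lost their call without those arrays, many at a change of like size, such as Asns (0.65), Oplah (0.95), Ppbp (1.09), Derl3 (0.80), Il1f9 (0.63), Gsr (0.44), Ccl17 (-0.51) and Cyp51 (0.45). Smaller changes were left in Fdps (0.29), Fdft1 (0.31), Fads2 (0.37) and Dnajb9 (0.29). The 6 lists placed higher kept their calls and the 5 placed lower lost theirs. Of the latter the medians of conventional dendritic cell markers (-0.13), neutrophil markers (-0.12) and macrophage markers (-0.03) stayed about as large, that of the chemokines shrank to -0.04 and that of the interferon genes turned to 0.02. When the PA and mock arrays alone were fitted, Slc7a5 (adjusted p = 0.122), Creld2 (0.0815), Il1rn (0.0748), Irf7 (0.136), Marco (0.0997) and Taar7d (0.0551) lost theirs, as Slc7a5 and Irf7 did without several single arrays. Slc7a5 also lost its limma call with the replicate number as a block (adjusted p = 0.0564). Leaving out mock replicate 1 gave 201 calls, mock replicate 2 gave 170, PA replicate 3 gave 220 and PA replicate 4 gave 192.

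IMQ alone raised inflammatory genes and lowered genes of the cell cycle, lipid metabolism and antigen presentation. By the same rule the 6 largest rises were in Il6 (5.03 ± 0.88, adjusted p = 0.000232), the neutrophil chemokine Cxcl3 (4.67 ± 0.89), the interferon-inducible Ifi205 (4.62 ± 0.35), the triglyceride synthesis enzyme Dgat2 (4.58 ± 0.29), the interleukin 12 subunit Il12a (4.58 ± 0.26) and Tmc3 (4.52 ± 0.17). The largest falls were in Mamdc2 (-5.83 ± 0.14, adjusted p = 3.72e-14), the monocyte chemokine receptor Ccr2 (-4.56 ± 0.14), Gask1b (-3.93 ± 0.17), the diacylglycerol lipase Daglb (-3.84 ± 0.07), the lectin Clec4b1 (-3.71 ± 0.17) and the adhesion protein tensin (Tns1, -3.71 ± 0.13). The IMQ means of Ccr2 (4.73), Gask1b (4.44) and Clec4b1 (2.14) and the mock mean of Tmc3 (3.97) lay below 4.93, the level under which 95% of sensory receptor genes lie, so these changes are lower bounds of size and the order is that of the measured values. Limma called 7727 genes, 3766 higher and 3961 lower, and 1138 changed by at least 1 on the log2 scale. The spread of Il6 among the mock arrays entered its estimate, and without the arrays over the share limit, which left 1 mock array with Il6 at 4.32, below that level, its change was at least 7.59. Without those arrays Cxcl3 rose by at least 8.10, Ifi205 by 6.02, Dgat2 by 5.81, Il12a by 5.61 and Tmc3 by at least 5.17. Without mock replicate 4 alone the rises were 4.18 for Il6, 3.52 for Cxcl3, 4.15 for Ifi205, 4.17 for Dgat2, 4.24 for Il12a and at least 4.30 for Tmc3, so their order depends on the IMQ-type signal in the mock arrays.

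All 16 genes of the NF-kB target list rose with IMQ, including the prostaglandin synthase Ptgs2 (4.50 ± 0.88, and 3.63 without mock replicate 4), the nitric oxide synthase Nos2 (4.45 ± 0.48) and the feedback inhibitor Socs3 (3.15 ± 0.11). Of the cytokines 15 of 16 rose, with Tnf (2.98 ± 0.08), Il12b (2.76 ± 0.12), Il1b (2.41 ± 0.36) and Il10 (2.08 ± 0.14, a lower bound, with a mock mean of 4.08). Il1b read 13.1 on the IMQ arrays, near the highest value on any array (13.5), so its rise may be understated. Il23a, the subunit particular to IL-23, had a mock mean of 4.50, below the level of 4.93, and rose by at least 0.68 ± 0.11 (adjusted p = 0.000101), a call lost without the arrays over the share limit (0.43, adjusted p = 0.0795). Chemokines rose in 14 of 15, among them Cxcl1 (4.39 ± 0.44), and type I interferon stimulated genes in 17 of 18, with Ifit1 (3.17 ± 0.11), Oasl1 (2.94 ± 0.11) and Isg15 (2.75 ± 0.11). Dendritic cell maturation genes rose in 12 of 14 and fell in 2, with Cd40 (2.38 ± 0.09) and Tnfsf9 (2.17 ± 0.08) among the rises. In the PERK-ATF4 list 19 of 21 rose and 1 fell, with the growth inhibitor Ddit4 (2.69 ± 0.10), Asns (2.63 ± 0.06), Slc7a5 (2.13 ± 0.08), Trib3 (1.86 ± 0.07) and Ddit3 (1.18 ± 0.07) higher and Atf3 lower (-0.71 ± 0.04). These 6 lists were called by camera with medians from 1.18 to 2.49 and held with an estimated correlation. Without the arrays over the share limit the rises were 7.10 for Ptgs2, 6.20 for Nos2, 5.87 for Cxcl1 and 3.73 for Il1b. The ER folding list was not called (adjusted p = 0.209). It had 12 genes higher and 6 lower of 24, with Derl3 (0.79 ± 0.12) and Dnajb9 (0.55 ± 0.06) higher and Sdf2l1 lower (-0.95 ± 0.06). Hspa5, the chaperone BiP, rose by 0.21 ± 0.06, a call lost when quantile normalization was repeated (0.16, adjusted p = 0.0571) and, at a change no smaller, when the arrays over the share limit were left out (0.24, adjusted p = 0.13), and Xbp1 was not called (0.04 ± 0.04).

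Of the 22 cell cycle genes 21 fell with IMQ, among them the cyclins Ccna2 (-2.58 ± 0.15, a lower bound of size, with an IMQ mean of 4.57) and Ccnb2 (-2.17 ± 0.12), and 1 rose. Cholesterol synthesis genes fell in 15 of 16 and rose in 1, with Dhcr7 (-1.70 ± 0.09) and Cyp51 (-1.04 ± 0.07). Fatty acid oxidation and PPAR target genes fell in 12 of 19, including the fatty acid binding protein Fabp4 (-3.47 ± 0.07), Cpt1a (-1.15 ± 0.05) and Plin2 (-0.55 ± 0.05), while Hilpda, a lipid droplet protein, rose (1.14 ± 0.06). MHC class II presentation genes fell in 8 of 10 and rose in 2, with the peptide exchange factor H2-DMa (-1.83 ± 0.06) and the class II transactivator Ciita (-1.36 ± 0.08) lower. All 4 lists were called by camera and held with an estimated correlation. Camera also called 6 lists that were lost with one. These were glycolysis (11 of 14 higher and 1 lower, adjusted p = 0.0967 with an estimated correlation), with the regulator Pfkfb3 (1.47 ± 0.05) and the glucose transporter Slc2a1 (0.71 ± 0.04), and NRF2 targets (6 higher and 3 lower of 12, adjusted p = 0.417 with an estimated correlation), with Gsr (1.08 ± 0.05) and Hmox1 (0.44 ± 0.04) higher and Nqo1 lower (-1.01 ± 0.08). On the lower side they were ribosomal proteins (8 of 14, adjusted p = 0.212), macrophage markers (8 of 12, adjusted p = 0.202), fatty acid synthesis (8 of 11, adjusted p = 0.417) and oxidative phosphorylation (9 of 22, adjusted p = 0.43), each p being the one with an estimated correlation. Among the macrophage markers the mannose receptor Mrc1 fell (-3.62 ± 0.06) and Marco rose (3.04 ± 0.10). Adjusted over the list alone, the calls in either direction were 20 of 21 for PERK-ATF4, 15 of 16 for cytokines, 14 of 15 for chemokines, 16 of 16 for NF-kB targets and 18 of 18 for interferon genes. They were 14 of 14 for maturation, 10 of 10 for MHC class II, 22 of 22 for the cell cycle, 16 of 16 for cholesterol and 14 of 19 for fatty acid use. For the ER folding, glycolysis, NRF2, ribosomal, macrophage, fatty acid synthesis and oxidative phosphorylation lists they were 19, 12, 10, 10, 11, 10 and 12.

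Adding PA to IMQ raised Il23a 8.21-fold (log2 change 3.04 ± 0.11, limma adjusted p = 2.15e-11) and genes of protein folding in the endoplasmic reticulum. The other largest rises were in Lrrc32, which encodes the surface protein GARP that holds latent TGF-beta (3.71 ± 0.10), Penk, the enkephalin precursor (3.47 ± 0.10), Fos (3.40 ± 0.07), Sptssb, a subunit of the serine palmitoyltransferase that starts sphingolipid synthesis (at least 3.26 ± 0.17, with an IMQ mean of 3.31, below 4.93), and Derl3 (3.05 ± 0.12). The largest falls were in the signal-regulatory proteins Sirpb1c (-2.98 ± 0.13) and Sirpb1a (-2.25 ± 0.05), the inhibitory lectin Siglece (-2.30 ± 0.11), the lubricin gene Prg4 (-2.21 ± 0.18), the cholesterol hydroxylase Ch25h (-2.18 ± 0.06) and the receptor Klra2 (-2.12 ± 0.10). Limma called 4676 genes, 2583 higher and 2093 lower, and 256 changed by at least 1 on the log2 scale, 187 of them higher.

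The ER folding list had 21 of 24 genes called higher and 0 lower when PA was added to IMQ (median log2 change 0.67, camera adjusted p = 4.18e-26, and 0.00854 with an estimated correlation). Its largest rises besides Derl3 were Sdf2l1 (1.82 ± 0.06) and Creld2 (1.68 ± 0.05), and Hspa5 rose by 1.25 ± 0.06. Xbp1, whose spliced form drives such genes and whose splicing these gene-level values do not resolve, was not called (0.09 ± 0.04). It was called higher by limma with dim genes left out (adjusted p = 0.0403) and with a variance trend and robust moderation (adjusted p = 0.0136). In the PERK-ATF4 list 13 of 21 genes fell and 6 rose (median -0.35, adjusted p = 0.378 with an estimated correlation). The amino acid metabolism genes Cth (-1.29 ± 0.17) and Asns (-0.90 ± 0.06) and the secreted Stc2 (-1.06 ± 0.10) were lower, while Ddit4 (0.80 ± 0.10), Atf3 (0.60 ± 0.04) and Ddit3 (0.55 ± 0.07) were higher. Trib3 (-0.22 ± 0.07) was called at an adjusted p = 0.0468, and lost that call with equal array medians, with array weights and without several single arrays.

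Cytokine genes went both ways with PA added, 7 of 16 higher and 3 lower, and the list was not called (camera adjusted p = 0.11). It was called higher when the IMQ and IMQ with PA arrays alone were fitted (adjusted p = 0.0389) and without the arrays over the share limit (adjusted p = 0.0390), but not with an estimated correlation (adjusted p = 0.577). Besides Il23a, the growth factor genes Csf3 (2.74 ± 0.17) and Lif (1.66 ± 0.12) and the interleukin 12 and 23 subunit Il12b (0.55 ± 0.12) rose, and Tnf fell (-0.62 ± 0.08). Il1b (0.02 ± 0.36) and Il10 (-0.26 ± 0.14) were not called. Il1b read 13.1 to 13.2 on all arrays with IMQ, near the highest value on any array (13.5), so a further rise may not be resolved. The error of Il1b also holds the spread of the arrays without IMQ. Il6 (0.35 ± 0.88) was not called either, with the spread of the arrays without IMQ in its error, and was called when the IMQ and IMQ with PA arrays alone were fitted (adjusted p = 0.0019). Chemokines (3 higher and 2 lower of 15, with Cxcl10 at 0.75 ± 0.13), NF-kB targets (3 higher and 2 lower of 16) and type I interferon genes (3 higher and 5 lower of 18) were not called as lists. Nor were dendritic cell maturation genes (5 higher and 3 lower of 14), though the costimulatory ligand genes Cd86 (0.97 ± 0.07) and Tnfsf4 (0.97 ± 0.08) and the maturation marker Cd83 (0.76 ± 0.05) rose and Tnfsf9 fell (-0.60 ± 0.08). The errors of chemokines and NF-kB targets that differed among the arrays without IMQ also hold that spread. The counts for these lists may therefore miss changes.

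NRF2 targets rose in 8 of 12 and fell in 2 (median 0.55), with Gclc (1.70 ± 0.06), Nqo1 (1.64 ± 0.08) and Srxn1 (1.42 ± 0.05), and Hmox1 by 0.44 ± 0.04. Fatty acid oxidation and PPAR target genes rose in 11 of 19 and fell in 1, with Hilpda (2.44 ± 0.06), Cpt1a (0.98 ± 0.05), the fatty acid transporter Cd36 (0.94 ± 0.04) and Plin2 (0.85 ± 0.05). The p53 and apoptosis list rose in 8 of 12 and fell in 1 (median 0.21). All 3 lists held with an estimated correlation (adjusted p = 0.0377, 0.0318 and 0.0484). Cholesterol synthesis genes rose in 7 of 16, with Insig1 (0.58 ± 0.05) and Fdps (0.54 ± 0.08), a camera call lost at an adjusted p = 0.188 with an estimated correlation. Also lost were the lower calls of ribosomal proteins (7 of 14, adjusted p = 0.0902 with an estimated correlation), glycolysis (6 of 14, with Pfkfb3 at -0.57 ± 0.05 and Ldha at -0.34 ± 0.04, adjusted p = 0.378 with an estimated correlation) and macrophage markers (8 of 12, adjusted p = 0.0993 with an estimated correlation). Of the macrophage markers the Fc receptor Fcgr1 (-0.89 ± 0.05), the scavenger receptors Msr1 (-0.79 ± 0.04) and Marco (-0.53 ± 0.10) fell and Mrc1 rose (1.05 ± 0.06). The fatty acid synthesis list was not called, with the desaturase Scd1 lower (-0.70 ± 0.06). Histidine decarboxylase (Hdc), listed with the mast cell and basophil markers, rose by 2.46 ± 0.23, and that list was not called. Adjusted over the list alone, the genes called were 23 of 24 for ER folding, 20 of 21 for PERK-ATF4, 11 of 12 for NRF2, 13 of 19 for fatty acid use and 10 of 12 for p53 and apoptosis. They were 9 of 16 for cholesterol, 9 of 14 for ribosomal proteins, 7 of 14 for glycolysis, 12 of 12 for macrophage markers and 10 of 16 for cytokines.

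**Figure D3:**
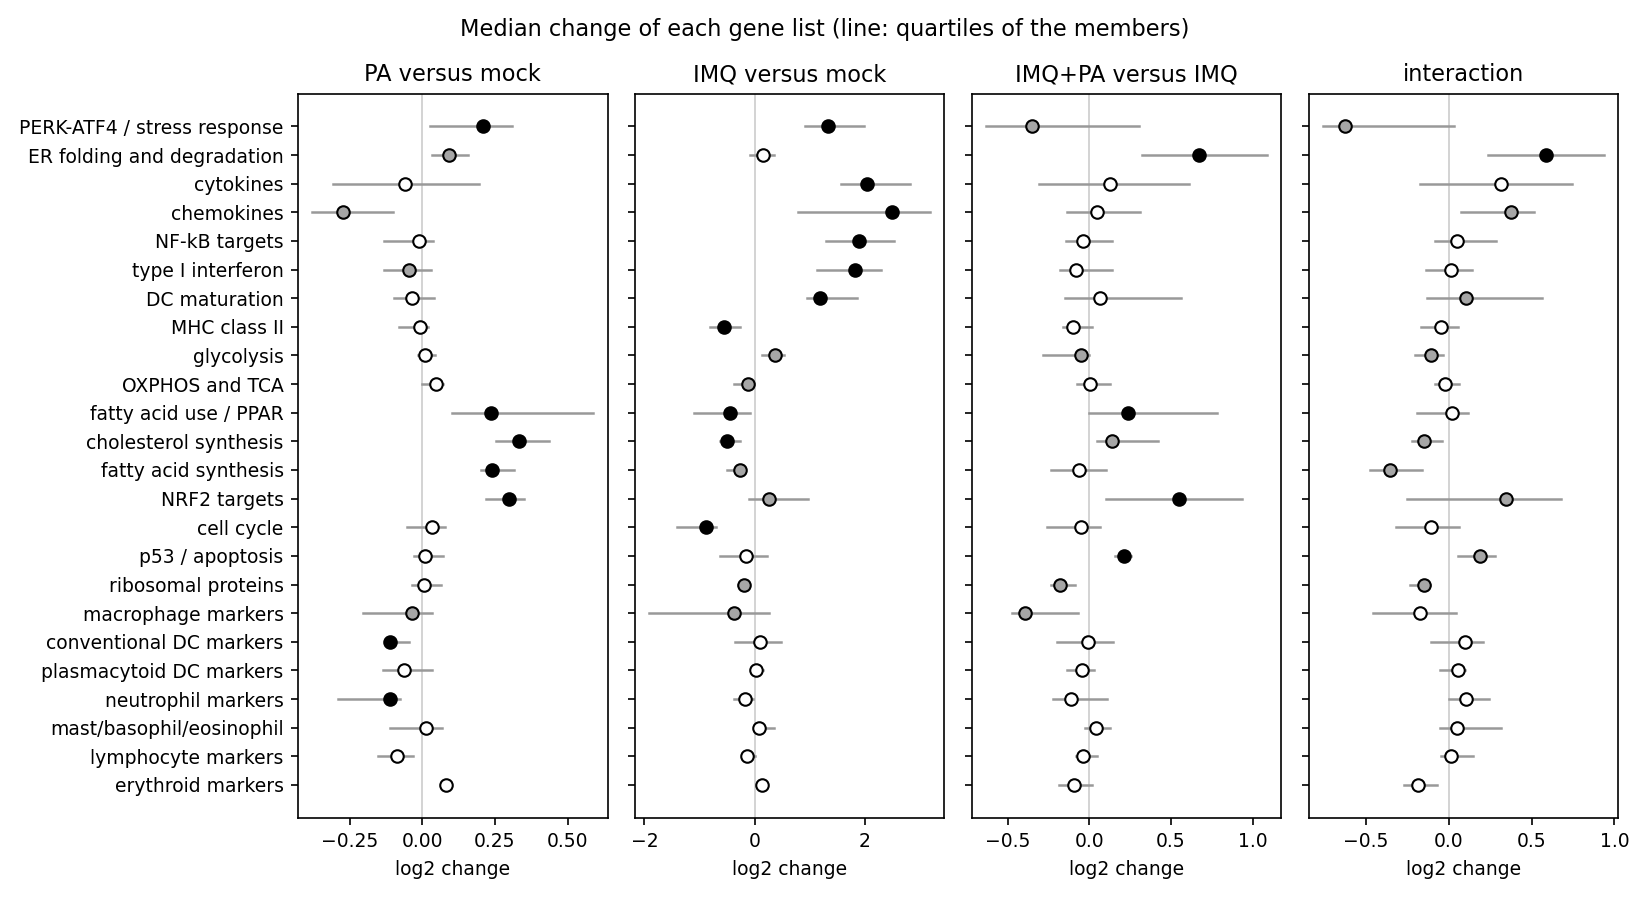
Median log2 change (horizontal axes) of each of 24 gene lists (vertical axis) in 4 comparisons, with lines from the lower to the upper quartile of the members. Black points passed camera with both the preset and the estimated correlation, grey points only the preset one and white points neither. The ER folding list stands at 0.67 for IMQ and PA versus IMQ and at 0.09 for PA versus mock.

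IMQ in the presence of PA gave a response of like size to IMQ alone, with 7836 genes called by limma, 3722 higher and 4114 lower, and 1247 changed by at least 1 on the log2 scale. The largest rises were in Il6 (6.31 ± 0.88), the gap junction gene Gja1 (5.30 ± 0.26), Cxcl3 (5.23 ± 0.89), Ptgs2 (5.23 ± 0.88), Cxcl1 (5.23 ± 0.44) and Nos2 (5.15 ± 0.48). These sizes rest on PA arrays that differed among themselves. The rise of Il6 was 5.71 without PA replicate 1, 5.67 without PA replicate 2, 7.07 without PA replicate 4 and at least 8.20 without the arrays over the share limit. That of Ptgs2 was 4.63, 4.59, 5.99 and 7.09 in the same order, and that of Cxcl3 was 5.83 without PA replicate 4 and 6.59 without the arrays over the limit, where Gja1 rose by 5.95, Cxcl1 by 6.03 and Nos2 by 5.93. The largest falls were in Mamdc2 (-5.22 ± 0.14), Ccr2 (-4.78 ± 0.14), Clec4b1 (-3.87 ± 0.17), Pgap1 (-3.83 ± 0.09), Pld4 (-3.70 ± 0.04) and the amino acid transporter Slc36a2 (-3.63 ± 0.13). The changes of Ccr2 and Clec4b1 are lower bounds of size, with means of 4.56 and 2.09 in IMQ with PA, below 4.93. Il23a rose by at least 3.73 ± 0.11, with a PA mean of 4.49, and Il12b by 3.33 ± 0.12. All 16 cytokine genes and all 16 NF-kB targets rose, as did 14 of 15 chemokines and 17 of 18 type I interferon genes. The ER folding list rose in 22 of 24 (median 0.62, adjusted p = 0.0218 with an estimated correlation) and the PERK-ATF4 list in 17 of 21 (median 0.96). The cell cycle list fell in 21 of 22 and cholesterol synthesis in 15 of 16, and ribosomal proteins fell in 12 of 14 (adjusted p = 0.0385 with an estimated correlation). Camera called 17 of 24 lists, and 13 of them held with an estimated correlation. The lost ones were NRF2 targets (10 of 12 higher and 1 lower, adjusted p = 0.0593 with an estimated correlation), glycolysis (9 higher and 2 lower of 14, adjusted p = 0.292), oxidative phosphorylation (4 higher and 14 lower of 22, adjusted p = 0.417) and fatty acid synthesis (1 higher and 9 lower of 11, adjusted p = 0.188). Adjusted over the list alone, 23 of 24 ER folding genes, 17 of 21 PERK-ATF4 genes and 12 of 14 ribosomal protein genes were called.

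The 2 IMQ comparisons share no arrays. Of the 3766 genes higher with IMQ versus mock, 2512 were also higher with IMQ and PA versus PA, where independent lists would share 632, and 114 were lower. Of the 3961 lower genes 2933 were lower in both, against 735 for independent lists, and 126 were higher. The correlation of the 2 sets of log2 changes was 0.83 across genes, which are not independent replicates. The 2 PA comparisons also share no arrays, with the same limit. Of the 233 genes PA raised without IMQ, 130 were higher with it (27.1 for independent lists) and 38 lower, and of the 98 lower genes 23 were lower with it (9.25 for independent lists) and 3 higher. Their log2 changes correlated at 0.13 across genes.

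The interaction asks whether the PA change differed with IMQ. Limma called 3015 genes, 1460 with a higher and 1555 with a lower PA change in the presence of IMQ, and 230 of them by at least 1 on the log2 scale. With the share as a covariate and all arrays kept, 2561 were called, 2373 of them among the 3015. Without the arrays over the share limit, which left 1 mock array, Il6 had a difference of 0.61. Its values on the arrays without IMQ left there, 4.32 at most, lay below 4.93, so that size is approximate. Calls lost there, with 5 arrays fewer, were those of Cth (-1.03, adjusted p = 0.115), Cxcl10 (0.69, 0.0504), H2-DMa (-0.37, 0.151), Il12b (0.29, 0.0932), Ddit3 (0.40, 0.116), Trib3 (-0.49, 0.12) and Hmox1 (0.34, 0.0937). Against the fit of all arrays the difference was about as large or larger in Cth (-1.04), Ddit3 (0.31), Trib3 (-0.45) and Hmox1 (0.32), and smaller in Cxcl10 (0.86), H2-DMa (-0.47) and Il12b (0.57). The largest positive differences were in Lrrc32 (3.73 ± 0.15, adjusted p = 3.36e-10), Penk (3.30 ± 0.14), Sptssb (3.07 ± 0.24), Il23a (3.05 ± 0.16, adjusted p = 3.95e-09), Il2 (2.80 ± 0.23) and the metalloproteinase gene Mmp19 (2.79 ± 0.07). In Sptssb, Il2 and Il23a both groups without IMQ had means below 4.93, so their PA change without IMQ is not resolved and the size of the difference is approximate. Lrrc32 fell from a mean of 8.81 in mock to 5.61 with IMQ and stood at 9.32 with both. The largest negative differences were in Sirpb1c (-2.97 ± 0.19), Sirpb1a (-2.18 ± 0.08), Ch25h (-2.17 ± 0.08), Siglece (-2.08 ± 0.15), Klra2 (-2.03 ± 0.14) and the ADP receptor P2ry13 (-2.02 ± 0.11). Siglece had a PA mean of 4.85 and P2ry13 a mean of 4.89 in IMQ with PA, both below 4.93. The mean of Ch25h was 8.01 in mock, 7.99 with PA, 10.47 with IMQ and 8.29 with both.

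Among the lists, ER folding had 18 of 24 genes with a higher PA change in the presence of IMQ and 1 with a lower one (median 0.59, camera adjusted p = 4.54e-23, and 0.00854 with an estimated correlation), and it was the only list of the 10 called that held with an estimated correlation. The PERK-ATF4 list had 14 of 21 lower and 4 higher (median -0.63, adjusted p = 0.0593 with an estimated correlation), with Asns (-1.43 ± 0.08), Stc2 (-1.09 ± 0.15) and Cth (-1.04 ± 0.24, with both groups without IMQ below 4.93) lower and Ddit4 higher (0.81 ± 0.13). NRF2 targets had 7 of 12 higher and 3 lower, with Gclc (1.35 ± 0.09) and Nqo1 (1.29 ± 0.12) higher and Gsr lower (-0.59 ± 0.07; adjusted p = 0.196 with an estimated correlation for the list). Fatty acid synthesis had 6 of 11 lower and 1 higher, with Scd1 (-0.97 ± 0.09) and Fads2 (-0.75 ± 0.11; adjusted p = 0.196 with an estimated correlation for the list). The remaining 6 calls, all lost with an estimated correlation, were chemokines, maturation genes and the p53 list on the higher side and glycolysis, cholesterol synthesis and ribosomal proteins on the lower, with adjusted p from 0.105 to 0.43 under that setting. With the share as a covariate, chemokines (median -0.055, camera adjusted p = 0.735), maturation genes (0.036, 0.0733) and the p53 list (0.145, 0.0621) lost their calls. Their medians had been 0.37, 0.10 and 0.19, and the share was computed in part from chemokines. Without the arrays over the share limit the medians were 0.14, 0.03 and 0.18 in the same order. The fatty acid oxidation and PPAR target list was not called, with Angptl4 lower (-1.76 ± 0.19) and Hilpda higher (1.62 ± 0.08). The PA changes of Cpt1a (-0.10 ± 0.08) and Plin2 (-0.18 ± 0.07) did not pass the test of a difference, nor did those of Xbp1 (0.08 ± 0.05), Il10 (-0.15 ± 0.20), Il1b (0.38 ± 0.51) and Il6 (1.28 ± 1.25). Tnf (-0.81 ± 0.11) and Hspa5 (1.05 ± 0.08) did. Il1b lay near the highest value of any array in both groups with IMQ, so a difference may be hidden. Adjusted over the list alone, 22 of 24 ER folding, 18 of 21 PERK-ATF4, 11 of 12 NRF2 and 9 of 11 fatty acid synthesis genes were called.

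The lists of MHC class II, oxidative phosphorylation, plasmacytoid dendritic cell, lymphocyte and erythroid genes were not called with PA alone, with PA added to IMQ, or in the interaction. Of the markers of other cell types, 0 of 9 lymphocyte genes were called in any comparison, and with IMQ versus mock 2 of 5 erythroid genes rose, 2 of 7 plasmacytoid dendritic cell genes rose and 1 fell, and 5 of 15 mast cell, basophil and eosinophil genes rose and 1 fell. The same comparison called 5 of 10 conventional dendritic cell genes higher and 4 lower, with a median of 0.09, a mean of -0.07 and a camera direction upward, and 3 of 13 neutrophil genes higher and 4 lower, with a median of -0.18, a mean of 0.06 and a camera direction downward. The p53 and apoptosis list (4 higher and 7 lower of 12) was not called there, and the cell cycle list (3 higher and 5 lower of 22) was not called with PA added to IMQ. For the cytokine list with PA alone the median (-0.06) and mean (-0.09) lay below 0 and the camera direction was upward. With PA added to IMQ, the interferon list had a median of -0.08, a mean of 0.00 and a downward direction, and the NF-kB list had a median of -0.04, a mean of 0.01 and a downward direction.

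**Figure D4:**
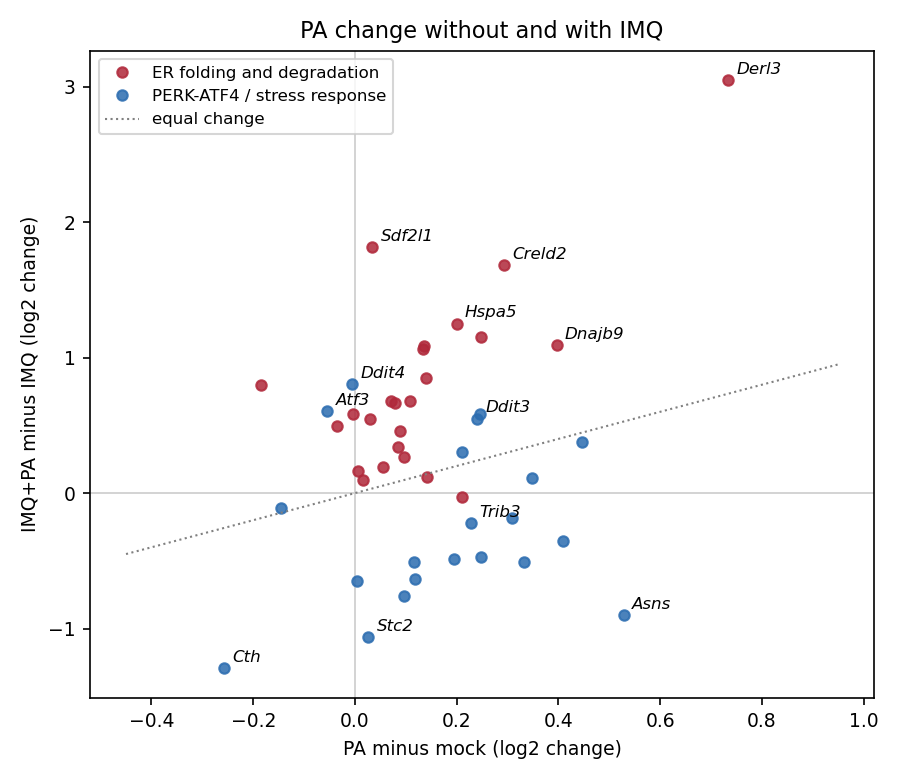
Log2 change with PA in the absence of IMQ (horizontal axis) and in its presence (vertical axis) for each measured gene of the ER folding list (red) and the PERK-ATF4 list (blue), with a dotted line at equal change. Derl3 stands highest at 3.05, and 13 of the 21 PERK-ATF4 genes were called lower in the presence of IMQ.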

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

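The tests of carry-over, of a ceiling and of the cell mix were chosen after the result was seen.

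Single arrays stood apart from the other 3 of their group in 22 of 412 gene and group pairs, since the gap to the nearest array, divided by the group's range (in brackets), was above Dixon's 95% limit for 4 samples, which chance gives in about 1 in 20 groups. Of these, 9 were mock replicate 4 as the lowest, in Taar7d (0.885), Il6 (0.908), Il1b (0.894), Cxcl3 (0.897), Il12a (0.899), Ptgs2 (0.873), Nos2 (0.920), Socs3 (0.897) and Hdc (0.878). The other 13 were Fads2 in IMQ replicate 2 (lowest, 0.890), Psat1 in IMQ replicate 1 (highest, 0.900), Derl3 in IMQ with PA replicate 2 (lowest, 0.852), Ccl17 in IMQ with PA replicate 3 (highest, 0.944), Gask1b in IMQ with PA replicate 2 (lowest, 0.832), Clec4b1 in IMQ replicate 3 (highest, 0.851), Cd40 in IMQ with PA replicate 4 (lowest, 0.847), Slc7a5 in IMQ with PA replicate 4 (lowest, 0.854), Dhcr7 in mock replicate 1 (lowest, 0.900), Siglece in IMQ replicate 4 (lowest, 0.895), Prg4 in IMQ replicate 4 (lowest, 0.876), Il2 in PA replicate 4 (highest, 0.983) and Stc2 in IMQ with PA replicate 4 (highest, 0.882).

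The PA change differed with IMQ by the limma interaction test in 62 of the 103 named genes. It was higher with IMQ by at least 1.5 on the log2 scale in Lrrc32 (3.73), Penk (3.30), Sptssb (3.07), Il23a (3.05), Il2 (2.80), Mmp19 (2.79), Csf3 (2.52), Hdc (2.43), Fos (2.39), Derl3 (2.31), Gja1 (2.00), Sdf2l1 (1.78), Hilpda (1.62), Taar7d (1.59) and Lif (1.54). Smaller positive differences were found in Creld2 (1.39), Gclc (1.35), Nqo1 (1.29), Olfr1537 (1.22), Srxn1 (1.15), Hspa5 (1.05), Mrc1 (1.00), Cxcl10 (0.86), Tnfsf4 (0.84), Cd83 (0.82) and Ddit4 (0.81), and in Cd86 (0.77), Dnajb9 (0.69), Atf3 (0.66), Oasl1 (0.64), Mamdc2 (0.61), Il12b (0.57), Ccl17 (0.47), Cd36 (0.41), Hmox1 (0.32) and Ddit3 (0.31). It was lower with IMQ in Sirpb1c (-2.97), Sirpb1a (-2.18), Ch25h (-2.17), Siglece (-2.08), Klra2 (-2.03), P2ry13 (-2.02), Angptl4 (-1.76), Prg4 (-1.48), Pld4 (-1.48), Asns (-1.43), Stc2 (-1.09), Ppbp (-1.05) and Cth (-1.04), and by less than 1 in Scd1 (-0.97), Tnf (-0.81), Fcgr1 (-0.79), Slc7a5 (-0.76), Fads2 (-0.75), Msr1 (-0.75), Gsr (-0.59), Tnfsf9 (-0.57), Pfkfb3 (-0.51), Pgap1 (-0.49), H2-DMa (-0.47), Trib3 (-0.45) and Ldha (-0.37). The call of Il12b was lost with the replicate number as a block (adjusted p = 0.0571), that of Ddit3 with equal array medians (adjusted p = 0.0798), and both in most fits that left out 1 array. Without the arrays over the share limit, with 5 arrays fewer, the calls of Cth (-1.03, adjusted p = 0.115), Ddit3 (0.40, 0.116), Trib3 (-0.49, 0.12) and Hmox1 (0.34, 0.0937) were lost at a difference about as large or larger, and those of Cxcl10 (0.69, 0.0504), H2-DMa (-0.37, 0.151) and Il12b (0.29, 0.0932) at a smaller one. In Sptssb, Il2, Il23a, Cth, Hdc, Taar7d and Olfr1537 both groups without IMQ had means below 4.93, the level of sensory receptor genes, so these sizes are approximate.

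The 1st pattern was IMQ-type signal in arrays without IMQ, which set 3 mock and 2 PA arrays apart. A small share of RNA or cells in the state of the IMQ group could account for it. With arrays divided by the 21 inflammatory and interferon list genes alone, the same 5 were over 2%, and in the 54 other IMQ-raised genes their lowest median share was 2.12% against at most 0.932% in the remaining 3. Carry-over of RNA, a few cells exposed to IMQ and a few cells activated without it would all raise both sets of genes. Plain mixing with the IMQ group would give both sets about the same share. Medians in list and other genes were 4.6% and 3.6%, 5.6% and 4.2%, and 5.3% and 5.2% in mock replicates 1 to 3. In PA replicates 3 and 4 they were 3.6% and 2.1%, and 5.7% and 2.9%. The shares were thus most even in mock replicate 3 and least even in the PA arrays. These gaps were not tested against the spread between genes, so the causes were not separated. In PA versus mock the calls went from 331 to 15 without those arrays, with 1 mock and 2 PA arrays left, and to 225 with the share as a covariate, so the loss to 15 cannot be put down to the signal alone.

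The 2nd pattern was the shift of the ER folding list upward and of the PERK-ATF4 list downward in the interaction, of which the PERK-ATF4 call was lost with an estimated correlation (camera adjusted p = 0.0593) and the ER folding call held. After the median of genes of like brightness was taken off, the gap between the list medians was 1.26 against 1.22 before. Quantile normalization already holds shifts shared by genes of like brightness small, and the median interaction over all genes was -0.014. This test could therefore hardly have lowered the gap, and it does not exclude an effect of the normalization. A ceiling on genes already raised by IMQ would not lower them, and 13 of 21 PERK-ATF4 genes were lower in IMQ with PA than in IMQ. A changed mix of cells was left open, since the macrophage markers had a median change of -0.40 with 8 called lower and 2 higher. No biological explanation was tested.

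The 3rd pattern was the 38 dim genes called lower with PA alone. Dim genes were about as common among the lower calls as among all genes tested, and rarer among the higher calls. They were a larger part of these lower calls than of those in the other comparisons, such as 187 of 2093 for IMQ with PA versus IMQ. The median change of the 38 was -0.47, a value inflated by their choice as called genes. All sensory receptor genes had a median change of -0.047, and with equal array medians all lower calls went from 98 to 60, so a small array-wide drop on the PA arrays was not excluded. In the arrays with IMQ the same genes had a median PA change of -0.011, with 21 of 38 below 0 and 3 called lower. The falls may come from differences between these mock and PA arrays other than a response to PA.

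A chance division of the arrays was excluded in every comparison at 1 in 20. Of the 35 splits of the 8 arrays, 1 (the real one) had as many calls in each, with 331 against at most 27 for PA versus mock, 7727 against 0 for IMQ versus mock, 4676 against 1 for IMQ with PA versus IMQ and 7836 against 1 for IMQ with PA versus PA. For the interaction, 1 of 100 regroupings of the residuals, the real one, had as many, with 3015 against at most 1.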

How the results depend on the processing

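Alternatives other than leaving out 1 array kept 2437 values of named genes and 1316 list values on their side of the threshold. Called values among these also kept their direction, which was not compared where neither fit gave a call. Another 54 and 50 lost their call, 11 and 33 gained one in either direction, and 2 list values called before reversed. Leaving out 1 array at a time kept 2441 values of named genes and 1136 list values in the same sense, with 55 and 8 calls lost, 0 and 8 gained and none reversed. With a change of at least 1 on the log2 scale required, 8 genes were left for PA versus mock, 1138 for IMQ versus mock, 256 for IMQ with PA versus IMQ, 1247 for IMQ with PA versus PA and 230 for the interaction, fewer by construction. For PA versus mock the calls went from 331 to 541 without genes dim by the median of all probe set means. They went to 737 with a variance trend and robust moderation and 150 with only the groups compared, and the cause was not tested. Of the 331 calls 70.4% were higher, against 81.6% (266 higher and 60 lower) with equal array medians and 62.8% (196 and 116) with repeated quantile normalization. Without single arrays they ranged from 170 to 346 for PA versus mock, 7199 to 7662 for IMQ versus mock, 3969 to 4647 for IMQ with PA versus IMQ, 7401 to 7556 for IMQ with PA versus PA and 2600 to 2897 for the interaction. Both alternatives on the IMQ-type share were chosen after seeing the data. Without the arrays over the limit 15 genes were left for PA versus mock and 1200 for the interaction, with fewer arrays, and the lists called were 7 and 6. The type I interferon list with PA alone reversed to 0.0521 with the share as a covariate and to 0.0248 without those arrays, and was called in neither. With an estimated correlation 7 lists were called for PA versus mock, 10 for IMQ versus mock, 4 for IMQ with PA versus IMQ and 1 for the interaction. With fry 14 were called for IMQ with PA versus IMQ and 18 for the interaction, a test that does not compare a list with other genes. With the replicate number as a block the calls were 259, 7721, 4655, 7885 and 2942 in the order of the comparisons above. The numbers were not taken as pairs, since the labels do not say that groups share them. In deviations from group means 7 of 16 arrays correlated best with an array of their own number. The 24 same-number pairs had a median correlation of 0.0057 (-0.118 to 0.173), against -0.0039 for different numbers. No chance level was computed for the 7, so these values do not exclude pairing. With 4 arrays per group, 67.2% of simulated changes of 0.5 were recovered for PA versus mock, so small changes with PA may be missed. Whether signal near background in 8614 dim genes adds to this was not tested.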

Other observations

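Gene families were looked at after their values were seen, so only counts of limma calls and log2 changes are given and no test of a family is claimed. Of 60 genes of ER translocation and early secretory transport, 44 were called higher and 0 lower in IMQ with PA versus IMQ, among them the coat gene Sec24d (0.96) and the translocon gene Sec61g (0.82), while 4 were higher and 0 lower with PA alone. Of 17 immediate-early genes 11 were higher and 0 lower in IMQ with PA versus IMQ, including Fos (3.40), the nuclear receptors Nr4a1 (2.58), Nr4a2 (2.16) and Nr4a3 (1.73), and Egr2 (1.40). With PA alone 1 of them was higher and 1 lower. In the Ms4a family of membrane proteins 7 of 20 were lower and 0 higher, with Ms4a14 (-1.53), Ms4a6b (-1.37) and Ms4a6c (-1.32). With PA alone 0 of the 20 were called, and their median change was -0.08 against -0.16 with PA added to IMQ.

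With IMQ versus mock all 10 guanylate-binding protein genes were higher, led by Gbp5 (3.58). Of 38 genes of proteasome subunits and assembly factors 32 were higher and 2 lower, with Psma6 (1.38) and the immunoproteasome subunit Psmb9 (0.85) among the rises. In the Cd300 receptor family 7 of 9 were lower and 1 higher, with Cd300lb at -3.66 and Cd300e at 1.53. Of 21 genes of the vacuolar proton pump 12 were lower and 1 higher, with Atp6v0d2 at -2.87, and of 31 genes with Clec names 12 were lower and 5 higher.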
